A study of Mus musculus with 7 samples.

How the data were processed

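RNA-seq was read from 7 libraries of sorted mouse uterine tumor epithelium, 3 from neutrophil-sufficient and 4 from neutrophil-deficient mice. Groups were taken from the labels. Replicates were numbered in accession order, and these numbers pair no libraries. The labels speak of 1 mouse per library but give no litter, cage, estrous stage, sequencing run or date, so neither batches nor stage could be examined.

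The deposited values stand in 2 tables of the whole series. The first table holds raw read counts per gene that the authors made, and it was the input of every main test. The second table holds a normalized signal per gene that the authors made by dividing the counts by 1 factor per library. In every library the ratio of raw to normalized values was constant to a relative deviation of 2.04e-06 or less and equalled the DESeq2 median-of-ratios size factor computed here. Per the submitters' processing notes, bcl2fastq, STAR, Picard, HTSeq and DESeq2 were used with the mouse build mm10. Their versions, the gene annotation and the strand setting of the counting are not given in the sources used here. Without a stated strand, reads of a gene and of an overlapping antisense gene cannot be told apart, and reads that fit several near-identical genes may have been dropped or assigned to 1 copy.

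The count table has 38683 rows, of which 12463 are at 0 in every library. It holds no row for unassigned reads. Names of 27 rows had been turned into dates by a spreadsheet, and these rows were kept in the library totals and tests but are not named. A further 4 rows carry 2 duplicated names and were left out of the tests. The table has 0 rows for the mitochondrially encoded transcripts, so the list of 13 such genes was not analysed here. Total counts per library ran from 20120384 to 54327223, and 14986 genes that hold 99.9% of the counts passed the expression filter. Intervals on counts are from a Poisson test on the reads pooled over each group. They cover counting error only and leave out differences between mice. The reads also carry no molecular identifiers.

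Tests were run in R 4.3.3 with edgeR 4.0.16 (TMM factors, filterByExpr with a minimum count of 10 and a minimum total of 15, robust glmQLFit and glmQLFTest on group). P-values were for both directions and adjusted by the method of Benjamini and Hochberg, with a threshold of 0.05. The standard error (SE) of a log2 fold change is the fold change divided by the square root of its F statistic. Fold changes are of the neutrophil-deficient over the neutrophil-sufficient group. The common biological coefficient of variation was 0.124. Levels are TMM-scaled CPM (counts scaled to a common library total), given as mean and SD. Before the data were examined, 34 gene lists with 557 symbols were fixed, and 32 of them had at least 3 tested members. These were tested with camera in limma 3.58.1 (preset inter-gene correlation of 0.01), with camera using an estimated correlation, and with fry. The level of a list in a library is the mean of log2(CPM + 1) over its members. List levels and summed CPM were compared by an exact permutation test over the 35 assignments of the libraries to groups of 3 and 4, on the absolute difference of means, whose smallest p is 0.0286.

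Named genes were chosen by a rule also set before the data were examined. It takes Csf3r, Pten and Pgr. It takes the 10 genes with the largest increase and the 10 with the largest decrease among called genes with an average log2 CPM of at least 1 and no overlap between groups. It takes the 5 genes with the smallest p, up to 4 members of each list with the smallest p, and Cxcl1, Cxcl2, Cxcl5, Vegfa, Slc2a1 and Car9 in any case. Genes named outside this rule are said to be chosen after their values were seen. Gene positions are from GENCODE release M21 for GRCm38, the assembly that mm10 names. A position was found for 14802 of the 14986 tested genes, 649 of them through a synonym. Msmo1 of the cholesterol list is counted under its older name Sc4mol. For annotated pseudogenes, the most similar protein-coding transcript was sought with BLAST 2.17.0, with at least 90% identity over at least 50% of the pseudogene.

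The fit was tested on counts simulated from these 7 libraries and its fit covered 14802 genes. It recovered 60 of 100 genes changed 1.5-fold and 83 of 100 changed 2-fold, and 12 of its 155 calls were false. The changed genes were drawn from those with a mean above 1 CPM, with the variation estimated by the same fit. The recovery therefore does not cover genes of lower expression. Alternatives tried were DESeq2 1.42.0, other scalings, other filters, a non-robust fit, limma-voom, a test against a 1.5-fold change, limma-trend on log2 of the authors' normalized values + 1, 1 surrogate variable from sva 3.50.0, leaving out each library, and, chosen after the totals were seen, thinning every library to the smallest total. Figures, positions and similarity searches used Python 3.11.15.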

Results

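The mice carried Pgr(cre/+) and Pten(lox/lox), a genotype in which Cre recombinase made from the progesterone receptor gene deletes the tumor suppressor Pten in the uterus. The 3 neutrophil-sufficient libraries came from mice with this genotype alone. The 4 neutrophil-deficient libraries came from mice that also lacked both copies of Csf3r, the receptor for granulocyte colony-stimulating factor (G-CSF), the main growth factor of neutrophils. At 4 weeks of age, uteri were digested and cells were sorted as negative for CD45, a surface protein of leukocytes, positive for CD326 (Epcam), an epithelial adhesion protein, and negative for the dead-cell dye 7-AAD. Their RNA was sequenced and counted per gene. The neutrophil-sufficient libraries held 54327223, 22582263 and 20120384 counts, and the neutrophil-deficient libraries 31336847, 23716233, 21442403 and 22640254. Correlations of log2 CPM were 0.990 to 0.992 within the sufficient group, 0.984 to 0.992 within the deficient group and 0.973 to 0.988 between groups. The first principal component, with 64.3% of the variance of the 500 most variable genes, separated the groups, and the deficient libraries were more widely spread on it (5.08 to 24.9) than the sufficient ones (-21.0 to -19.1). Replicates differed by more than counting noise, with a chi-squared per degree of freedom of 6.91 to 36.0 over the pairs of libraries within a group.

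The one comparison asked how the tumor epithelium of neutrophil-deficient mice differs from that of neutrophil-sufficient mice. The title of the series concerns neutrophils and hypoxic tumor cells, which makes hypoxia genes part of the question. The targeted gene followed the labels in each library. Csf3r (chromosome 4, 126024550 to 126044440, GRCm38) had 345, 361 and 209 reads in the sufficient libraries and 18, 16, 13 and 10 in the deficient ones. Its log2 fold change was -4.22 ± 0.35 (SE, edgeR adjusted p = 0.00125). Pten (chromosome 19, 32757497 to 32826160), which is deleted in both groups, had 78.2 ± 2.98 CPM (SD, n = 3) and 71.9 ± 5.70 CPM (n = 4), a difference that did not pass the test (edgeR adjusted p = 0.344). Pgr (chromosome 9, 8899833 to 8968611), which carries Cre in both groups, had 69.2 ± 13.2 CPM and 65.6 ± 8.18 CPM (edgeR adjusted p = 0.762). A count per gene does not show which part of a gene is deleted.

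In the neutrophil-deficient libraries 11 of 18 genes of stratified squamous epithelium and 7 of 12 neutrophil markers were lower, 7 of 15 macrophage and myeloid markers were higher, and the hypoxia list did not pass its test. The other squamous, neutrophil and macrophage members did not pass, and the difference in summed CPM of the neutrophil markers did not pass (exact permutation p = 0.886). The squamous, neutrophil and macrophage calls, made with camera, were lost with an estimated correlation (adjusted p = 0.102, 0.207 and 0.207 with an estimated correlation). In all, 779 of 14986 tested genes passed the edgeR test at an adjusted p under 0.05, of which 375 rose and 404 fell in the deficient libraries. At least 2-fold changes were seen for 92 of the genes that rose and 165 of those that fell. The groups did not overlap in 23.3% of tested genes, against 5.71% by chance. The number of calls changed when 1 library was left out. It was 174, 194 or 184 without sufficient replicate 1, 2 or 3, each of which leaves the smaller group with fewer libraries. Without deficient replicate 1, 2, 3 or 4 it was 1005, 196, 553 or 842. Of the 59 genes that passed and were named by rule, 27 also passed without each library in turn.

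Of 18 tested members of the squamous epithelium list, 11 fell, 0 rose and 7 did not pass (median log2 fold change -1.14, camera adjusted p = 1.34e-21, adjusted p = 0.102 with an estimated correlation, fry adjusted p = 0.0146). The counts were 15 lower and 1 higher adjusted over the list alone. The keratin of non-keratinizing stratified epithelium Krt13 went from 152.8 ± 71.9 CPM (SD, n = 3) to 17.8 ± 5.94 CPM (n = 4), a log2 fold change of -3.10 ± 0.35 (edgeR adjusted p = 0.00662). The basal-layer keratin Krt15 went from 281.6 ± 53.2 to 83.5 ± 24.0 CPM (log2 fold change -1.75 ± 0.21, edgeR adjusted p = 0.00662). Krt16 fell from 32.7 ± 3.67 to 13.6 ± 1.17 CPM (edgeR adjusted p = 0.00125). Sprr1a, a precursor of the cornified envelope, fell from 213.0 ± 17.8 to 131.9 ± 13.8 CPM (edgeR adjusted p = 0.00625). Krt14, Krt16, Krt17, Krt6a and Krt6b are close relatives, and how shared reads were split among them is uncertain. Members that fell but lie outside the naming rule, picked after their values were seen, include Trp63, the master regulator of basal cells (-1.48 ± 0.22, edgeR adjusted p = 0.0119), and Krt5 (-1.73 ± 0.22, edgeR adjusted p = 0.00745). The number of members that fell was 6 without sufficient replicate 1, and 8 to 10 without any other library. Summed squamous CPM was 2544 ± 402.4 in the sufficient and 1141 ± 153.3 in the deficient libraries (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.124 over 13 cell type lists).

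**Figure D1:**
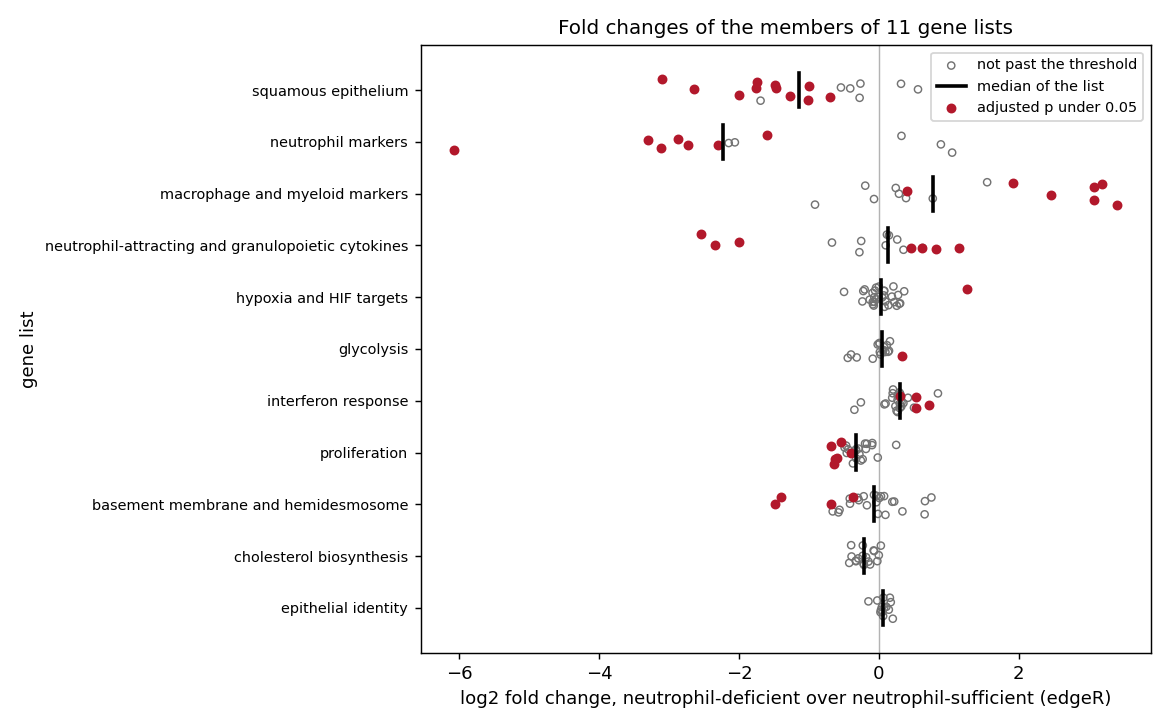
Log2 fold change (neutrophil-deficient over neutrophil-sufficient, edgeR, horizontal axis) of each tested member of 11 gene lists (vertical axis). Filled points passed an adjusted p under 0.05, open points did not, and the black bar is the list's median. Squamous and neutrophil members lie mostly to the left of 0 (medians -1.14 and -2.22), macrophage members mostly to the right (median 0.77), and hypoxia members on both sides of 0 (median 0.02).

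Of the 27 tested members of the basement membrane and hemidesmosome list, 4 fell and 0 rose (median -0.07, camera adjusted p = 0.00742, adjusted p = 0.648 with an estimated correlation). Adjusted over the list alone, 9 fell and 1 rose. Those called over all genes were the hemidesmosome collagen Col17a1 (118.8 ± 14.1 to 42.3 ± 16.5 CPM, edgeR adjusted p = 0.0251) and the anchoring fibril collagen Col7a1 (61.8 ± 3.91 to 38.5 ± 4.17 CPM, edgeR adjusted p = 0.00561), with Col4a6 (22.1 ± 2.20 to 8.26 ± 3.37 CPM, edgeR adjusted p = 0.0283) and the integrin Itga6 (572.8 ± 25.0 to 443.5 ± 19.9 CPM, edgeR adjusted p = 0.0254). The camera call of the basement membrane and hemidesmosome list was lost without sufficient replicate 2 (adjusted p = 0.0657). The number that fell was 2 without sufficient replicate 1, 1 without sufficient replicate 2 or 3 or deficient replicate 2, and 7 without deficient replicate 1. Col7a1 passed without each library in turn. The general epithelial identity list, with Epcam and the simple keratins, had 0 of 14 members past the threshold (median 0.06, camera adjusted p = 0.327, and 0.0419 for the epithelial identity list without sufficient replicate 2; adjusted p = 0.909 with an estimated correlation over the 7 libraries). Luminal markers (0 of 10, median -0.08, camera adjusted p = 0.709) and glandular markers (0 of 5, median 0.04 but mean -0.21, camera adjusted p = 0.88) did not pass either. Foxa2, a transcription factor of uterine glands, was at 15.7 ± 1.92 and 7.94 ± 3.09 CPM (edgeR adjusted p = 0.0740). In the ciliated cell list 2 of 8 members fell, Foxj1, the master regulator of motile cilia (2.92 ± 0.59 to 1.34 ± 0.38 CPM, edgeR adjusted p = 0.0390), and Mlf1 (edgeR adjusted p = 0.0345). Its median was -0.39 and its camera adjusted p was 0.0369 (adjusted p = 0.442 with an estimated correlation, fry adjusted p = 0.0284). The count adjusted over the list alone was 3 lower. The ciliated cells list lost its camera call without sufficient replicate 1 (0.111), without deficient replicate 1 (0.139) or with no filter on low counts (0.0811). Foxj1 lost its call without any 1 of the sufficient replicates or deficient replicate 2 or 3, and Mlf1 without any 1 of the 7 libraries. Summed ciliated CPM was 33.3 ± 0.0959 and 24.6 ± 1.94 (exact permutation p = 0.0286, adjusted p = 0.124 over 13 cell type lists).

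Although the sort was negative for CD45, myeloid transcripts were measurable. Of 12 tested neutrophil markers 7 fell, 0 rose and 5 did not pass (median log2 fold change -2.22, camera adjusted p = 1.21e-12, adjusted p = 0.207 with an estimated correlation, fry adjusted p = 0.0327). With p adjusted over the list alone, 9 fell and 1 rose. S100a8, a calcium-binding protein abundant in neutrophils, went from 12.02 ± 5.87 to 1.64 ± 0.29 CPM (log2 fold change -2.87 ± 0.31, edgeR adjusted p = 0.00362). Trem1, an activating receptor of myeloid cells, went from 5.87 ± 3.01 to 0.59 ± 0.17 CPM and Cxcr2, the receptor for neutrophil-attracting chemokines, from 2.34 ± 0.66 to 0.34 ± 0.11 CPM (edgeR adjusted p = 0.00362 for both). Stfa2l1, a member of a family of near-identical stefins and for that reason uncertain, had 87 reads over the sufficient libraries and 1 over the deficient ones, a ratio per count of 88.9 (95% interval 15.5 to 3550, counting error only). Members that did not pass, named after their values were seen, included Ly6g (0.32, edgeR adjusted p = 0.379), a surface protein of mouse neutrophils, and the integrin Itgam, which macrophages also carry (57.2 ± 13.0 and 105.2 ± 52.6 CPM, log2 fold change 0.89, edgeR adjusted p = 0.220). Itgam was a large part of the summed neutrophil CPM, which was 124.8 ± 41.4 and 123.3 ± 51.2 (exact permutation p = 0.886).

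Of 15 tested macrophage and myeloid markers 7 rose, 0 fell and 8 did not pass (median 0.77, camera adjusted p = 1.59e-10, adjusted p = 0.207 with an estimated correlation, fry adjusted p = 0.0284). When adjusted over the list alone, 9 rose and 1 fell. The 3 chains of complement C1q, which tissue macrophages make, rose with log2 fold changes of 3.08 ± 0.39 (C1qa, edgeR adjusted p = 0.00505), 3.19 ± 0.47 (C1qb, edgeR adjusted p = 0.0103) and 3.41 ± 0.55 (C1qc, edgeR adjusted p = 0.0148). Levels were low, from 0.44 ± 0.13 to 3.88 ± 1.37 CPM for C1qa, 0.48 ± 0.25 to 4.58 ± 1.86 CPM for C1qb and 0.36 ± 0.25 to 4.02 ± 1.69 CPM for C1qc. The 3 genes lie next to each other on chromosome 4 (136880129 to 136898803), between 10 and 20 Mb from Csf3r. They may therefore not be separate observations. Lysozyme Lyz2 rose from 2.56 ± 0.61 to 14.2 ± 2.87 CPM (edgeR adjusted p = 0.00125). Gpnmb, a glycoprotein of lysosome-rich macrophages (0.47 ± 0.20 to 10.8 ± 4.90 CPM, edgeR adjusted p = 0.00662), and the macrophage elastase Mmp12 (0.85 ± 0.41 to 6.98 ± 1.93 CPM, edgeR adjusted p = 0.00378) were also among the 10 largest increases. The number of macrophage members that rose was 3 without sufficient replicate 1, when the calls of C1qb and C1qc ended, and 4 without sufficient replicate 2 or 3 or deficient replicate 2 or 3. The call of Gpnmb, which is not in the list, also ended without sufficient replicate 1. Summed macrophage CPM was 480.4 ± 36.4 and 600.6 ± 67.0 (exact permutation p = 0.0857). The C1q chains and Lyz2 were a small part of this sum, which mostly reflects other members of the list.

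**Figure D2:**
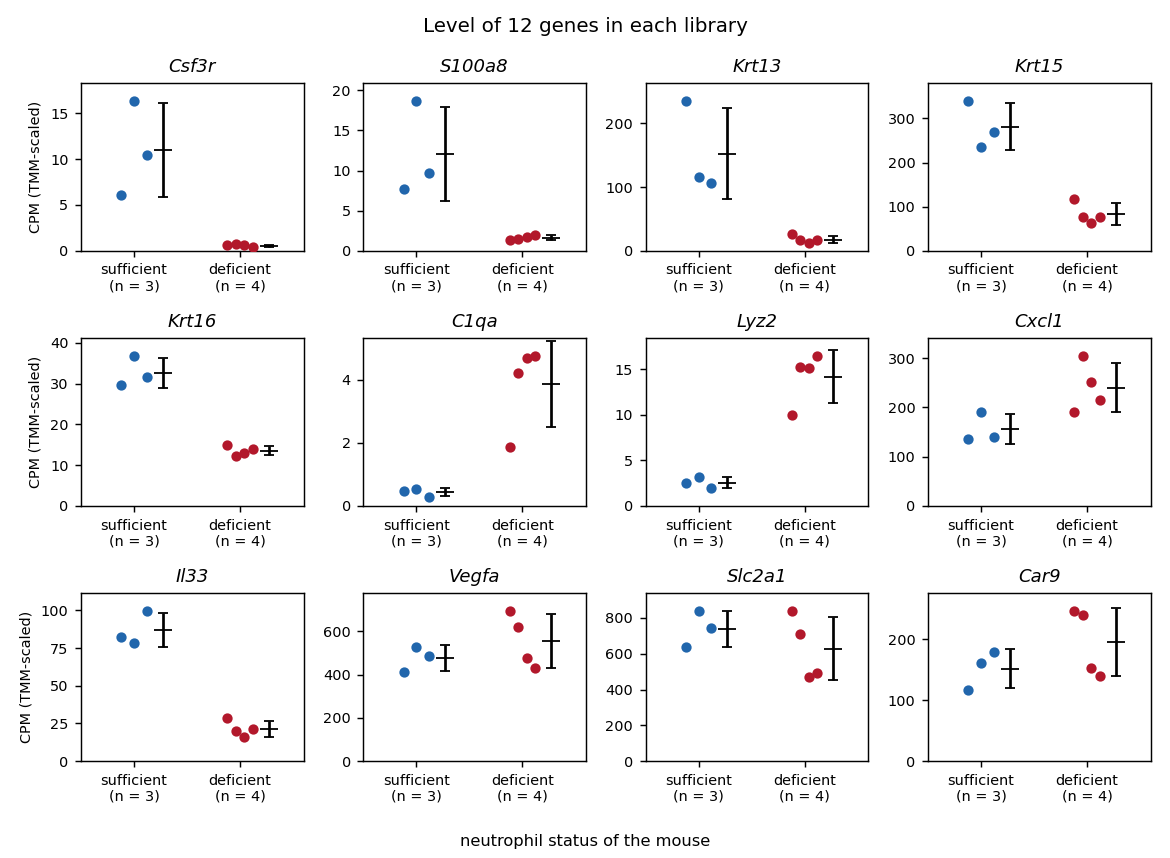
TMM-scaled CPM (vertical axes, each from 0) of 12 genes in each library of the neutrophil-sufficient (blue, n = 3) and neutrophil-deficient (red, n = 4) groups. Horizontal bars and whiskers are the mean and SD. Csf3r, S100a8, the keratins Krt13, Krt15 and Krt16, and Il33 were lower in each deficient library than in any sufficient one, C1qa and Lyz2 were higher, and the hypoxia-induced genes Vegfa, Slc2a1 and Car9 overlapped between groups.

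Cytokine genes that attract or sustain neutrophils went both ways: of 16 tested, 4 rose and 3 fell (median 0.13 but mean -0.21, camera adjusted p = 0.709, fry adjusted p for changes in either direction = 5.39e-05). The counts adjusted over the list alone were 6 higher and 3 lower. The alarmin Il33 fell (86.7 ± 11.3 to 21.5 ± 5.27 CPM, log2 fold change -2.01 ± 0.17, edgeR adjusted p = 0.00192). So did the chemokine Ppbp (28.0 ± 5.00 to 5.44 ± 2.08 CPM, edgeR adjusted p = 0.00502) and Il1b (43.9 ± 19.1 to 7.52 ± 1.75 CPM, edgeR adjusted p = 0.00649). Il1b is also made by neutrophils. The epithelial cytokine Il17c rose (25.0 ± 4.71 to 44.2 ± 6.11 CPM, edgeR adjusted p = 0.0159). The others that rose, named after their values were seen, were Csf2 (log2 fold change 1.15 ± 0.25, edgeR adjusted p = 0.0364), Tnf (0.62 ± 0.14, edgeR adjusted p = 0.0432) and Ccl20 (0.46 ± 0.11, edgeR adjusted p = 0.0406). The 3 decreases were called without each library in turn. The number of increases was 0 without sufficient replicate 1 or 3, 2 without sufficient replicate 2 and 1 without deficient replicate 2. Of the Cxcr2 ligands named by rule, Ppbp fell and the others did not pass. Cxcl1 was at 155.5 ± 30.6 and 240.1 ± 49.3 CPM (edgeR adjusted p = 0.0766). Cxcl2 was at 482.2 ± 101.3 and 522.3 ± 88.6 CPM (edgeR adjusted p = 0.708) and Cxcl5 at 852.3 ± 120.9 and 715.7 ± 182.2 CPM (edgeR adjusted p = 0.465). Among 22 tested NF-kB and acute inflammatory genes, the hydrogen peroxide-producing oxidase Duox1 (edgeR adjusted p = 0.00908) and the antimicrobial lectin Reg3g (edgeR adjusted p = 0.0474) fell and 0 rose (median 0.11 but mean -0.07, camera adjusted p = 0.517; adjusted over the list alone, 2 rose and 2 fell). Reg3g lost its call without any 1 of the sufficient replicates or deficient replicate 2 or 3.

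Of 32 hypoxia and HIF target genes, 1 rose, 0 fell and 31 did not pass (median log2 fold change 0.02, camera adjusted p = 0.455), and adjusted over the list alone the counts were the same. The one that rose was Angptl4, an inhibitor of lipoprotein lipase (6.37 ± 1.05 to 15.2 ± 3.99 CPM, log2 fold change 1.26 ± 0.22, edgeR adjusted p = 0.0159). Its call was lost without any 1 of the sufficient replicates or without deficient replicate 2. The angiogenic factor Vegfa was at 476.8 ± 58.4 and 555.9 ± 122.9 CPM (edgeR adjusted p = 0.445). The glucose transporter Slc2a1 was at 739.9 ± 99.2 and 628.7 ± 176.3 CPM (edgeR adjusted p = 0.512), and the carbonic anhydrase Car9 at 152.0 ± 32.1 and 195.1 ± 56.0 CPM (edgeR adjusted p = 0.386). The mean level of the list was 7.41 ± 0.10 and 7.45 ± 0.21 on the log2 scale (exact permutation p = 0.743), with deficient libraries at 7.66, 7.61, 7.33 and 7.22. The hypoxia and HIF targets list passed, as higher in the deficient group, without deficient replicate 4 (camera adjusted p = 0.0349) and with 1 surrogate variable in the model (0.00446). These calls rest on the preset correlation, and over the 7 libraries the list had an adjusted p = 0.909 with an estimated correlation. Of 18 glycolysis genes, 1 rose, Bpgm, the mutase that makes 2,3-bisphosphoglycerate (edgeR adjusted p = 0.0442), and 0 fell (median 0.04 but mean -0.00, camera adjusted p = 0.755). The counts adjusted over the list alone were the same, and the call of Bpgm was lost without any 1 library other than deficient replicate 4.

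Of 25 proliferation genes 6 fell in the deficient libraries, 0 rose, 19 did not pass and 24 had a negative fold change (median -0.33, camera adjusted p = 4.34e-09, adjusted p = 0.648 with an estimated correlation, fry adjusted p = 0.177). They included the mitotic kinase Cdk1 (75.2 ± 11.6 to 49.0 ± 5.10 CPM, edgeR adjusted p = 0.0192), its partner Ccnb1 (edgeR adjusted p = 0.0157) and the proliferation marker Mki67 (273.3 ± 9.04 to 207.5 ± 17.7 CPM, edgeR adjusted p = 0.0259). Adjusted over the list alone, 17 fell and 0 rose. The number that fell was 0 without sufficient replicate 1, sufficient replicate 2 or deficient replicate 2, and 3 without sufficient replicate 3. Of 26 interferon response genes 4 rose, 0 fell and 24 had a positive fold change (median 0.30, camera adjusted p = 8.72e-07, adjusted p = 0.648 with an estimated correlation). Adjusted over the list alone, 16 rose and 2 fell. Those called over all genes were the transcription factor Irf7 (165.1 ± 10.5 to 272.7 ± 59.8 CPM, edgeR adjusted p = 0.0359), the chemokine Cxcl10 (132.8 ± 2.87 to 192.7 ± 26.6 CPM, edgeR adjusted p = 0.0234), Isg15 (edgeR adjusted p = 0.0437) and Irf9 (edgeR adjusted p = 0.0497). Of these 0 passed without deficient replicate 2 or any 1 of the sufficient replicates. MHC class I genes had 0 of 12 past the threshold, with 12 positive fold changes (median 0.16, camera adjusted p = 0.0123, adjusted p = 0.668 with an estimated correlation, and 0.170 by camera for the MHC class I presentation list without sufficient replicate 1). In the MHC class II list 1 of 7 rose, the class II transactivator Ciita (3.29 ± 0.72 to 6.10 ± 0.80 CPM, edgeR adjusted p = 0.0305; list median 0.52, camera adjusted p = 0.00918, adjusted p = 0.648 with an estimated correlation). The camera call of the MHC class II presentation list was lost without sufficient replicate 1 (0.0635) or deficient replicate 1 (0.0963) or with the filter of 10 CPM (0.243). Ciita lost its call without any 1 of the sufficient replicates or deficient replicate 2.

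Other lists passed camera with few or no single members past the threshold. The cholesterol synthesis list had a negative fold change in 16 of 18 genes (median -0.21, camera adjusted p = 0.000949, adjusted p = 0.648 with an estimated correlation), 0 of them called by edgeR over all genes and 7 lower adjusted over the list alone. The immediate early and dissociation stress list had a positive fold change in 16 of 18 genes (median 0.23, camera adjusted p = 0.00107, adjusted p = 0.648 with an estimated correlation). Of these 0 were called over all genes, and adjusted over the list alone 8 rose and 1 fell, with the transcription factor Egr1 at 566.7 ± 34.1 and 776.0 ± 110.8 CPM (edgeR adjusted p = 0.0516). Oxidative phosphorylation genes had 0 of 22 called (median 0.10, camera adjusted p = 0.0293, adjusted p = 0.855 with an estimated correlation). With 1 surrogate variable the oxidative phosphorylation list lost its call (0.203), as it did when leaving out sufficient replicate 1 (0.0863) or 3 (0.0696) or deficient replicate 3 (0.120) or 4 (0.0585). The red cell list had 0 of 5 called over all genes, 4 higher adjusted over the list alone and 5 positive fold changes (median 0.93, camera adjusted p = 0.00138, adjusted p = 0.648 with an estimated correlation). Summed red cell CPM was 43.4 ± 14.0 and 83.1 ± 23.2 (exact permutation p = 0.0286, adjusted p = 0.124 over 13 cell type lists), with the globin Hbb-bs at 26.9 ± 8.59 and 52.5 ± 13.8 CPM (edgeR adjusted p = 0.0766), and globin copies share reads. Smooth muscle markers had 1 of 9 higher, the enteric actin Actg2 (3.10 ± 0.77 to 7.06 ± 2.25 CPM, edgeR adjusted p = 0.0391; list median 0.61, camera adjusted p = 0.00141, adjusted p = 0.648 with an estimated correlation), and 3 higher adjusted over the list alone. The smooth muscle markers list lost its camera call without sufficient replicate 1 (0.0635), and Actg2 lost its own without any 1 library other than deficient replicate 1.

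Of the lists that did not pass camera, those of other cell types had few calls. Endothelial markers had 0 of 12 called (median 0.38, camera adjusted p = 0.0765), stromal fibroblast markers 0 of 15 (median 0.17, camera adjusted p = 0.283) and lymphocyte markers 0 of 3 (median -0.29, camera adjusted p = 0.709). Leaving out sufficient replicate 2 or deficient replicate 1 brought the endothelial markers list (0.00109 and 0.0326) and the stromal fibroblast markers list (0.00483 and 0.0115) past camera as higher, as did leaving out deficient replicate 4 for the endothelial list (0.0446). These too rest on the preset correlation, and over the 7 libraries both lists had an adjusted p = 0.909 with an estimated correlation. The 2 tested mesothelial markers (median 0.50, 0 called) were too few for a set test. In the epithelial-mesenchymal transition list the matrix protein Tgfbi (124.8 ± 23.4 to 50.01 ± 11.7 CPM, edgeR adjusted p = 0.0119) and the transcription factor Snai2 (edgeR adjusted p = 0.0445) fell among 12 (median -0.01, camera adjusted p = 0.259; 3 fell adjusted over the list alone). Tgfbi lost its call without sufficient replicate 1 and Snai2 without any 1 library other than deficient replicate 1. Of 21 matrix proteases and inhibitors Mmp11 rose (edgeR adjusted p = 0.0305; list median -0.07, camera adjusted p = 0.601), and adjusted over the list alone 2 rose and 4 fell. Of 21 cell-cell junction genes 0 were called (median -0.05, camera adjusted p = 0.517). The PI3K-AKT-FOXO list, the pathway that Pten restrains, had 1 of 18 lower, the kinase Akt3 (7.53 ± 0.53 to 3.74 ± 0.25 CPM, log2 fold change -1.01 ± 0.13, edgeR adjusted p = 0.00561; list median -0.02, camera adjusted p = 0.474). In the ovarian steroid response list the activin antagonist Fst fell (81.8 ± 13.1 to 30.96 ± 7.81 CPM, edgeR adjusted p = 0.00965), and the transcription factor Gata2 rose (edgeR adjusted p = 0.0423) among 15 (median 0.03 but mean -0.12, camera adjusted p = 0.928; 3 rose and 2 fell adjusted over the list alone). The p53 and senescence list had 1 of 18 lower, the death receptor Tnfrsf10b (edgeR adjusted p = 0.0447; list median -0.00, camera adjusted p = 0.455). The unfolded protein response list had 1 of 16 lower, Asns, which makes asparagine (edgeR adjusted p = 0.0260; list median -0.07, camera adjusted p = 0.332; 3 fell and 1 rose adjusted over the list alone). NRF2 targets had 0 of 17 called (median -0.06, camera adjusted p = 0.542). Of the single genes in these lists, Akt3 and Fst passed without each library in turn. Mmp11, Gata2, Tnfrsf10b and Asns lost their calls without any 1 of the sufficient replicates or deficient replicate 2. Mmp11 also lost its call without deficient replicate 3, and Tnfrsf10b without deficient replicate 3 or 4.

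Other genes named by rule for the size or the p of their change were of several kinds. The gel-forming mucin Muc5b (5.03 ± 3.60 to 0.14 ± 0.23 CPM, log2 fold change -4.89 ± 0.94, edgeR adjusted p = 0.0307) and Nccrp1 (6.16 ± 0.33 to 0.29 ± 0.21 CPM, -4.34 ± 0.43, edgeR adjusted p = 0.00251) fell most among them. Others that fell were Psca (10.6 ± 3.93 to 1.46 ± 0.86 CPM, edgeR adjusted p = 0.00920), Ankk1 (3.84 ± 0.45 to 0.51 ± 0.41 CPM, edgeR adjusted p = 0.0119) and the serine protease Tmprss11bnl (45.3 ± 9.53 to 6.82 ± 3.38 CPM, edgeR adjusted p = 0.00847). The C-type lectin receptor Clec4d, a member of the neutrophil list, fell from 4.75 ± 1.96 to 0.55 ± 0.34 CPM (edgeR adjusted p = 0.00745). Calml3, a calmodulin-like protein of epithelium, fell from 16.6 ± 2.69 to 2.85 ± 0.85 CPM (edgeR adjusted p = 0.00125). The sialyltransferase St8sia6 (2.35 ± 0.51 to 31.2 ± 21.1 CPM, edgeR adjusted p = 0.0236), Etnppl, which degrades phosphoethanolamine (2.57 ± 0.64 to 16.7 ± 7.32 CPM, edgeR adjusted p = 0.00908), and the acyltransferase Mogat1 (2.70 ± 0.21 to 11.1 ± 6.45 CPM, edgeR adjusted p = 0.0485) rose. The call of Muc5b was lost without sufficient replicate 1 or 2 or deficient replicate 2 or 3. That of St8sia6 was lost without any 1 of the sufficient replicates or deficient replicate 2, that of Mogat1 without these or deficient replicate 3, and that of Ankk1 without sufficient replicate 1.

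The smallest p of all genes belonged to a pair of processed pseudogenes, which are intronless copies of a parent gene. Gm11223 (chromosome 4, 69925630 to 69926079) rose from 1.47 ± 0.33 to 9.75 ± 0.48 CPM (log2 fold change 2.68 ± 0.17, edgeR adjusted p = 0.000397), and Gm10093 (chromosome 17, 78491582 to 78493025) from 3.06 ± 0.65 to 12.1 ± 0.49 CPM (1.95 ± 0.16, edgeR adjusted p = 0.00125). Their sequences are 99.8% and 99.4% identical to transcripts of Stmn1 (chromosome 4, 134468320 to 134473843) and Hdac1 (chromosome 4, 129516104 to 129542713), so these values are uncertain as expression of the pseudogenes. Stmn1 and Hdac1, named after the pseudogenes' values were seen, had log2 fold changes of -0.26 ± 0.07 (edgeR adjusted p = 0.0610) and -0.29 ± 0.07 (edgeR adjusted p = 0.0407). Genes within 10 Mb of Csf3r were called about as often as genes elsewhere, 16 of 299 (5.35%) against 757 of 14502 (5.22%), with a Fisher exact p of 0.895. Over all lists, 14 of the 32 tested passed camera, 8 up and 6 down, and 0 passed with an estimated correlation. By fry, 4 passed on direction (squamous, neutrophil, macrophage and ciliated) and 18 for changes in either direction.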

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

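A look for libraries that stand far from their group was planned before the data were examined, but as values without a test. The values checked include those of the named genes, most of which the naming rule picks by their test results. For the 4 deficient libraries, the gap of the highest or lowest library to its nearest neighbour was divided by the range of the group. In 13 of 186 values checked this share was above Dixon's critical value at 95%, where chance gives about 9.3, and single values past it are no evidence by themselves. The 3 sufficient libraries are too few for the rule.

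The level of the proliferation list in deficient replicate 3 was 5.68 against 5.89 to 5.91 in the others (share 0.908). The level of the immediate early and dissociation stress list was 9.33 in deficient replicate 2 against 9.11 to 9.14 (0.87). The level of the macrophage list was 2.63 in deficient replicate 1 against 2.998 to 3.038 (0.902), and C1qc in that library was at 1.502 CPM against 4.65 to 5.06 CPM (0.885). Also in deficient replicate 1, Muc5b was at 0.490 CPM against 0 to 0.0451 CPM (0.908), Col7a1 at 44.7 CPM against 35.9 to 37.1 CPM (0.867) and Pdgfra at 8.36 CPM against 12.3 to 13.0 CPM (0.858). In deficient replicate 3, Psmb8 was at 118.3 CPM against 101.4 to 103.5 CPM (0.877), Adamts1 at 62.9 CPM against 173.9 to 191.5 CPM (0.863), Pik3ip1 at 37.8 CPM against 22.6 to 24.1 CPM (0.899) and Esam at 8.43 CPM against 3.84 to 4.13 CPM (0.938). Gata2 was at 290.5 CPM in deficient replicate 2 against 233.5 to 238.7 CPM (0.908). Stfa2l1 was at 0.0437 CPM in deficient replicate 4, from 1 read, against 0 in the others (share 1).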

How the results depend on the processing

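Thinning every library to the smallest total was the one alternative chosen after the library totals were seen. It gave 654 genes. No result past the threshold changed direction under any alternative, whereas 4 comparisons of named genes and 25 of lists changed sign while past the threshold in neither setting. The number of genes past the threshold was 1629 (868 higher, 761 lower) with DESeq2, 1000 with limma-voom, 764 with RLE size factors, 824 with upper-quartile factors, 864 with library size only, 789 with the non-robust fit, 733 with the authors' normalized values, 702 with 1 surrogate variable, and 69 (21 higher, 48 lower) against a 1.5-fold change. Without a filter 598 genes were higher, and with the filter of 10 CPM in 3 libraries, which tests fewer genes, 470 were called and 217 lower. Without 1 library in turn the number ran from 174 (without sufficient replicate 1) to 1005 (without deficient replicate 1), with 55 to 485 higher and 106 (without deficient replicate 2) to 520 lower. Of the 174 genes, 166 were among the 779. The number of lists past camera was 0 with an estimated correlation and 4 with fry, and 9 (without sufficient replicate 1) to 16 (without sufficient replicate 2) when 1 library was left out. The neutrophil markers list had an adjusted p of 0.207 with an estimated correlation and passed camera without each library. The hypoxia and HIF targets list had an adjusted p of 0.00446 with 1 surrogate variable and 0.0349 (without deficient replicate 4) to 0.912 (without sufficient replicate 1) when 1 library was left out. The cause of these changes was not tested. Leaving out a library lowers the number of libraries, and the filter of 10 CPM lowers the number of tested genes, but neither was examined as a cause. Over 2837 comparisons of named genes with an alternative, 2528 kept their side of the threshold (those with a changed sign included), 122 passed newly and 187 no longer passed, and over the lists these counts were 580, 12 and 38. No paired analysis was possible because the replicate numbers follow only the order of deposition.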

Other observations

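Tests of mixed tissue, of less leukocyte RNA, of 1 neutrophil source, of neutrophil-like genes among those that fell, of the spread of the hypoxia list and of clustering on chromosome 8 were chosen after the results were seen, and so were the genes named in this part. The genes in this and the next paragraph lie outside the lists and were picked because they changed, so they say nothing of how other genes of their kind behaved. Those that fell in the deficient libraries include the transglutaminases Tgm1 (-1.69 ± 0.31, edgeR adjusted p = 0.0244) and Tgm5 (-2.13 ± 0.37, edgeR adjusted p = 0.0152), which cross-link the cornified envelope, and the desmosomal protein Pkp1 (-1.33 ± 0.25, edgeR adjusted p = 0.0260). Ly6d (-1.99 ± 0.26, edgeR adjusted p = 0.00639), Fat2 (-1.45 ± 0.18, edgeR adjusted p = 0.00561) and the basal-cell receptor Ngfr (-1.55 ± 0.18, edgeR adjusted p = 0.00372) also fell. The hyaluronan receptor Cd44 fell from 42.1 ± 0.342 to 11.9 ± 2.86 CPM (edgeR adjusted p = 0.00155), and the membrane-cytoskeleton linker Msn fell by 1.15 on the log2 scale (edgeR adjusted p = 0.00362).

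Genes picked from those that rose include the scavenger receptor Msr1 (3.25 ± 0.40, edgeR adjusted p = 0.00372), the lipid-sensing receptor Trem2 (2.81 ± 0.43, edgeR adjusted p = 0.00908), Siglec1 (2.60 ± 0.35, edgeR adjusted p = 0.00561) and the lipid transporter Cd36 (2.85 ± 0.61, edgeR adjusted p = 0.0339). Apoe, which many cells make, rose from 12.7 ± 1.76 to 45.2 ± 14.6 CPM (edgeR adjusted p = 0.0159). Others were the pyruvate dehydrogenase kinase Pdk4 (1.54 ± 0.33, edgeR adjusted p = 0.0307), the lipid droplet protein Plin4 (1.05 ± 0.26, edgeR adjusted p = 0.0473) and the acyl-CoA thioesterase Acot1 (0.95 ± 0.17, edgeR adjusted p = 0.0182). The mucosal chemokine Ccl28 rose from 95.7 ± 18.7 to 234.9 ± 57.9 CPM (edgeR adjusted p = 0.0159).

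The real grouping gave 779 genes and the other 34 splits of the 7 libraries into 3 and 4 at most 25 each. Thus 1 of 35 splits was as large, the real one, which is the smallest share this test can give. The other splits mix the groups, so a difference between the groups itself lowers their counts. A batch that follows the groups would give the same result. For the number of lists past camera, 14 in the real grouping against up to 18 in another split, chance cannot be excluded (17 of 35 splits as large). The camera -log10 p was largest in the real grouping for the squamous list (22.4, highest other 14.8) and the neutrophil list (13.1, highest other 8.41). The same held for the macrophage list (10.8, highest other 8.49). For each list this is 1 of 35 splits, the smallest share possible, and it is not adjusted over the lists. These lists also had the smallest camera p of the 32 tested. None of them passed camera with an estimated correlation (adjusted p = 0.102, 0.207 and 0.207). Their levels had an exact permutation p of 0.0286 each, the smallest possible, adjusted p = 0.135 over the lists. With only 35 assignments this adjusted p could hardly pass, so it does not decide the question. By fry the squamous, neutrophil and macrophage lists passed on direction (adjusted p = 0.0146, 0.0327 and 0.0284). The tests thus differ, and chance is not excluded for these lists.

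The lower squamous genes were first set against library depth, and after thinning every library to the smallest total 11 members of the list were still lower, which argues against depth as the cause. Squamous epithelium also lines the vagina and the lower cervix, so a different share of such tissue in the dissected uteri may give the same pattern. Reads of 6 genes of the posterior tract, Hoxa13 among them, summed to 7 in the sufficient and 3 in the deficient libraries, too few to tell. A difference of the tumor epithelium itself between the groups was not tested, and it and the share of tissue cannot be told apart here.

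Neutrophil and macrophage transcripts moved apart in cells sorted as negative for CD45. Less leukocyte RNA of every kind would lower both, but the macrophage list had a median log2 fold change of 0.7719, and depth is argued against by the 5 or more members of each list that still passed after thinning. The 7 neutrophil members that fell were all higher in sufficient replicate 2 than in replicate 1, with a median of 2.28-fold (log2 1.19, SD 0.215) that was at percentile 100 of 10000 random lists of like expression (median 0.00829), and Csf3r itself was 2.54-fold higher. This would follow from RNA of 1 neutrophil source in the sufficient sorts, which may also hold Csf3r transcripts, but it is not particular to neutrophils: sufficient replicate 2 was also above replicate 1 in the levels of the smooth muscle (3.51 and 2.75), stromal (5.34 and 4.91), endothelial (2.92 and 2.52) and mesothelial (1.73 and 1.23) lists, and the random lists do not allow for that. For the same reason the source of the genes that fell stays open, although outside the neutrophil list and at an average log2 CPM of at least 1, 13 of 333 of them (Csf3r, Il1b, Nlrp3 and Clec4e included) were at least 2 times higher in sufficient replicate 2 than 1, against 50 of 11544 that did not pass (Fisher exact p = 1.55e-08).

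The 5 pseudogenes that rose had their most similar coding gene within 10 Mb of Csf3r in 2 cases (40%), against 9 of 472 (1.91%) of those that did not pass (Fisher exact p = 0.004663). The 2 cases were Gm11223 and Gm10093, the pair with the smallest p of all tested genes. This pattern was read from the same results, and the test treats pseudogenes as independent, although some of the 9 share the parent Rps8. The Fisher p is therefore no separate support for a cause. Sequence variants of another mouse strain carried along with the Csf3r allele, which would send reads of Stmn1 and Hdac1 to Gm11223 and Gm10093, may account for these 2, and no genome sequence of such a strain was at hand to test this. More reads from the parents are argued against for these 2 by the log2 fold changes of Stmn1 and Hdac1 (-0.26 and -0.29). The coding genes matched to all 5 pseudogenes had a median of -0.1733 (SD 0.239), with 0 of 5 above 0.3. This median is the value of Zfp729a, matched at 92.5% identity to Pisd-ps2, a pseudogene named after Pisd. Pisd and Vps52, matched to Pisd-ps1 and Gm18734, had positive values (0.25 and 0.10), so the parents' part in the other pseudogenes stays open. Variants of another strain did not show as more called genes near Csf3r, with 16 of 299 within 10 Mb against 757 of 14502 elsewhere (Fisher exact p = 0.8953, and 0.528 and 0.751 for windows of 5 and 20 Mb).

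The hypoxia list was more widely spread among the deficient (SD 0.212) than the sufficient libraries (SD 0.0996), with an exact one-sided permutation p of 0.114 for the ratio of variances. The most crowded 10 Mb bin of called genes was chromosome 8 from 90 to 100 Mb, with 14 of 61 tested genes called (permutation p = 9e-04 over 10000 permutations). Those that rose were the carboxylesterases Ces1d (1.21), Ces1e (0.97), Ces1f (2.11) and Ces1g (1.87), a cluster of similar copies, and Irx3 (1.11), Irx5 (1.33), Gpr56 (0.56) and Kifc3 (0.59). Those that fell were Slc12a3 (-1.20), the metallothioneins Mt1 (-0.48) and Mt2 (-0.99), Lpcat2 (-0.84), Dok4 (-0.45) and Nup93 (-0.34). The permutations treated genes as independent, whereas neighbouring related genes such as the Ces1 copies and the metallothioneins may change together or share reads. The permutation p for this bin therefore does not show an effect of the region.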
